A study of Mus musculus with 8 samples.

How the data were processed

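H3K27ac ChIP and input DNA of mouse ectoplacental cone were sequenced at e7.5 and e9.5, with 2 libraries in each of 4 groups per the labels. Per the labels' protocols, chromatin was immunoprecipitated with a commercial H3K27ac antibody and libraries were made with the Illumina ChIP-seq protocol; the genome build is mm9 per the submitters' processing notes. The aligner, the peak caller, its thresholds and the way in which replicates were combined are not given in the sources used here. The deposited files used here are 4 peak lists, each for a stage and for H3K27ac or input; this assignment rests on the name each list was deposited under, since no list is tied to a library. The lists have no header. Other values in the deposited lists are the chromosome, start and end of each peak, taken as BED positions and printed counted from 1. The H3K27ac lists also hold a score per peak that the authors gave, in whole numbers from 21 upwards, with no stated unit. The score was used to describe, rank, band and filter the peaks of each list. The same bands were applied to both lists, shared regions were ranked by percentile ranks joined over the lists, and 1 test counted high-scoring peaks by the score of their partner in the other list, although no common scale of the lists is stated. The deposited input lists have no score.

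The values were checked before use. No peaks of a list overlapped each other, and within each H3K27ac list no gap between neighbouring peaks was under 500 bases. Peaks ran past the last gene of a GRCm38 gene table on 9 chromosomes, which does not by itself settle the build; mm9 was taken from the processing notes. As no annotation of mm9 was used here, the planned tests of promoter share, of genes per stage and of 16 gene lists fixed in advance were not made, and no gene is named. Depth is unknown, as the lists hold no counts, and intervals cover counting error over peaks only. Replicates cannot be compared, and stage cannot be told apart from any batch that went with it.

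An H3K27ac peak was called shared when it overlapped a peak of the other stage by at least 1 bp, and stage-only otherwise. Overlaps were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 and checked against bedtools 2.31.1, which gave the same counts for the 4 planned overlaps. Each observed share was set against 1000 random placements of the other list, with widths kept, within the span of each chromosome that holds peaks of any list (one-sided). Exact Clopper-Pearson intervals at the 95% level and Fisher's exact tests came from scipy 1.17.1. Neighbouring stage-only peaks were tested by permuting stage labels within chromosomes 100000 times. Distances to input were taken to the nearest input peak of either stage.

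Regions to be named were fixed before the data were examined, for the case without an annotation: the 10 highest-scoring stage-only peaks of each stage, ties by width, and the 10 shared regions that ranked highest by score; how the scores of both lists were joined, as the sum of percentile ranks, was chosen afterwards. The following alternatives were fixed at the same time: other overlap criteria, the higher-scoring part of each list, merging of peaks within 1 kb, autosomes only, lists of equal length, and lists without peaks on input. Score bands, clusters, megabase windows, long regions and the neighbour test were chosen after seeing the data.

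The procedures were tested on simulated data. With lists of the real lengths (7224 peaks in the tested list) and 10% planted sharing, the overlap test found 10.7%. With 50% planted it found 50.3%, while a pair of unrelated lists gave 0.581% (permutation p = 0.980). The simulated lists were placed at random in the same way as in the test, so unrelated lists whose peaks cluster were not simulated. With stage labels shuffled over the 6211 stage-only peaks, the neighbour test gave a permutation p under 0.05 in 1 of 20 runs. As the test itself permutes these labels, the runs check its rate of false calls only and not a local technical bias.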

Results

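The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from the mouse ectoplacental cone, the trophoblast tissue that grows out of the extraembryonic ectoderm and contributes to the invading part of the early placenta. The tissue was dissected free of maternal decidua and embryo from CD-1 mice, an outbred strain, on embryonic days 7.5 and 9.5. The antibody was raised against acetylated lysine 27 of histone H3 (H3K27ac), a modification found at active promoters and enhancers. The labels describe 8 libraries in 4 groups of 2 replicates, namely H3K27ac at e7.5, H3K27ac at e9.5 and the input DNA of each stage. The files used here are 1 peak list per group, with no value per replicate, so the spread between replicates could not be measured, and every test below describes these lists rather than the animals behind them. No read counts accompany the peaks, and sequencing depth is therefore unknown.

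The H3K27ac lists of both stages were close in size and shape. The e7.5 list held 7224 peaks over 8.82 Mb, with a median width of 854 bp, and the widest peak covered 16138 bp. The e9.5 list held 7620 peaks over 9004446 bp, with a median width of 861 bp and a widest peak of 13957 bp. Each H3K27ac peak carries a score given by the authors, whose meaning is not stated; it ran from 21 to 139 at e7.5 (median 28) and from 21 to 213 at e9.5 (median 27), and it is used here to describe, rank and filter the peaks of each list, and scores of different lists have no known common scale. The X chromosome held 134 e7.5 peaks and 123 e9.5 peaks, and no H3K27ac peak lay on the Y chromosome. The input lists differed far more, with 466 peaks over 0.117 Mb at e7.5 and 7499 peaks over 1.21 Mb at e9.5, at median widths of 186 and 121 bp.

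The first comparison asked how much of the H3K27ac landscape of the ectoplacental cone was kept between e7.5 and e9.5. Of the e7.5 peaks, 4313 of 7224 (59.7%) overlapped an e9.5 peak by at least 1 bp, and 2911 were called at e7.5 only. Of the e9.5 peaks, 4320 of 7620 (56.7%) overlapped an e7.5 peak, and 3300 were called at e9.5 only. Joined together, the lists made 10423 regions, of which 4212 held peaks of both stages. The bases common to both lists came to 5.06 Mb, or 57.4% of the e7.5 bases and 56.2% of the e9.5 bases (Jaccard index 0.396).

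The sharing was well above that of randomly placed peaks. When the e9.5 peaks were placed at random within their chromosomes 1000 times, 0.781% of the e7.5 peaks overlapped one on average and 1.09% at most (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Placing the e7.5 peaks instead gave 0.741% of the e9.5 peaks on average (one-sided permutation p = 0.001, again the smallest possible). Exact binomial 95% intervals ran from 58.6 to 60.8% for the e7.5 list and from 55.6 to 57.8% for the e9.5 list; they treat peaks as independent and cover counting error only. Among the autosomes the shared share ran from 55.7 to 67.0% of e7.5 peaks and from 53.3 to 61.3% of e9.5 peaks, and on the X chromosome it was 56.0 and 60.2%.

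The 10 shared regions with the highest scores in both lists were 328 to 2733 bp wide. Those ranked 1 to 7 were narrower than the median shared peak (1154 bp at e7.5, 1249 bp at e9.5), and those ranked 8 to 10 were wider. Ranked first was a region of 805 bp on chromosome 12, positions 60140547 to 60141351, which scored 132 in the e7.5 list and 213 in the e9.5 list. Second came 1087 bp on chromosome 5 (115939216 to 115940302), scoring 139 and 190 in the respective lists. Next was a region of 328 bp on chromosome 6 (121060189 to 121060516), with scores of 92.0 and 127. Chromosome 8 followed with 47772116 to 47772861 (scores 100 and 115), and chromosome 12 held another at 8647581 to 8648234 (101 and 110). The remaining 5 lay on chromosome 4 at 116861881 to 116862570, chromosome 11 at 83084553 to 83085013 and at 75272770 to 75274810, chromosome 1 at 167571826 to 167573419, and chromosome 10 at 90643192 to 90645924. Of these 10 regions, 1 (chromosome 12, 8647581 to 8648234) lay within 5 kb of an input peak. All positions are on the mouse build mm9 and counted from 1; no gene annotation of that build was used here, so regions are given by position and not by gene.

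Whether a peak was shared went with its score. Peaks at the bottom of the e7.5 list, scoring 21 or 22, were shared in 31.9% of cases (438 of 1374; 95% interval 29.4 to 34.4%). The share was 46.4% for scores of 23 to 26, 64.0% for 27 to 34 and 83.3% for 35 to 49. It reached 94.1% (480 of 510; 91.7 to 96.0%) for scores of 50 or more. The e9.5 list gave 25.5% (375 of 1469; 23.3 to 27.8%), 39.6%, 62.9%, 85.2% and 97.3% (621 of 638; 95.8 to 98.4%) over the same bands. Stage-only peaks were also narrower, with a median of 558 bp against 1154 bp for shared peaks at e7.5 and 570 bp against 1249 bp at e9.5. Their median score was 24.0 in either list, against 32.0 for shared peaks.

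**Figure D1:**
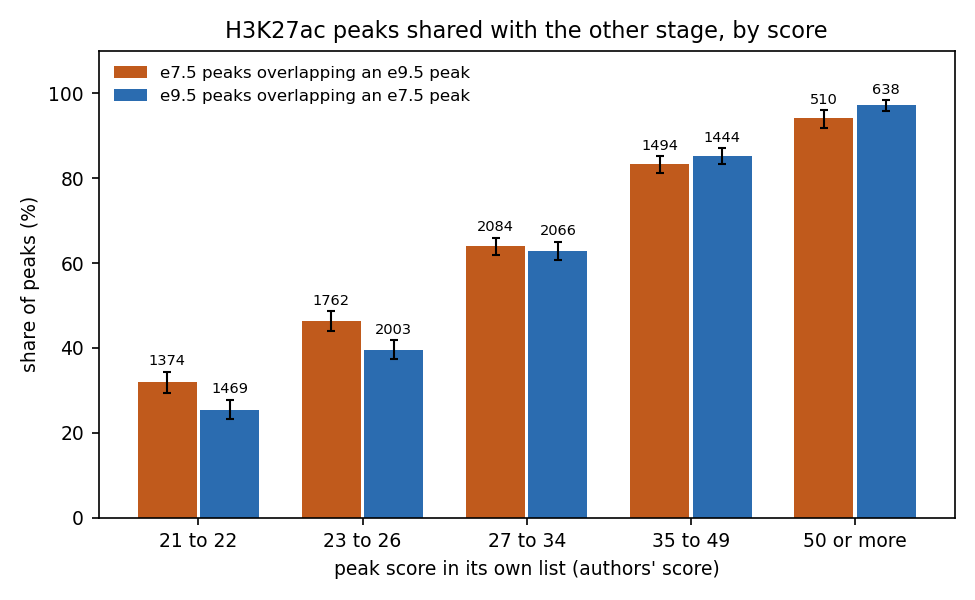
Share of H3K27ac peaks of each stage (vertical axis, percent) that overlap a peak of the other stage by at least 1 bp, by the peak's score in its own list (horizontal axis), with exact binomial 95% intervals as error bars and the number of peaks above each bar. The share rises from 31.9% to 94.1% for e7.5 peaks (orange) and from 25.5% to 97.3% for e9.5 peaks (blue).

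The second comparison asked which peaks were called at 1 stage only. The highest-scoring peak called at e7.5 only lay on chromosome 4, positions 132460821 to 132463305 (2485 bp, score 80.0), with the nearest e9.5 peak 35.5 kb away. Next was chromosome 5, 123585605 to 123588251 (score 75), 55.2 kb from the nearest e9.5 peak. A peak on chromosome 1, 135167134 to 135168319 (score 66.0), stood 95.6 kb from any e9.5 peak, and another on chromosome 5, 113595463 to 113596897 (score 59.0), stood 12.3 kb away. Peaks on chromosome 3 at 97670005 to 97671580 (score 70.0), chromosome 9 at 31086249 to 31087529 (score 62.0) and chromosome 2 at 93288915 to 93292337 (score 60.0) had an e9.5 peak at 6.76, 1.22 and 5.39 kb. The other 3 of the leading 10 lay within 5 kb of an input peak, on chromosome 12 at 53703797 to 53704752, chromosome 10 at 75360572 to 75362981 and chromosome 14 at 41726871 to 41728080. The chromosome 12 peak ended 0.123 kb from an e9.5 peak, so a slightly wider call would have made it shared.

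Among peaks called at e9.5 only, the most isolated of the leading 10 lay on chromosome 6, positions 122342199 to 122344791 (2593 bp, score 51.0), 415 kb from the nearest e7.5 peak. Chromosome 1 held a peak at 135829183 to 135831341 (score 56.0) with the nearest e7.5 peak 30.3 kb away, and chromosome 2 a peak of 506 bp at 152522176 to 152522681 (score 54.0) with the nearest at 13.4 kb. Peaks on chromosome 14 at 115441431 to 115442844 (score 67.0), chromosome 8 at 86721126 to 86723016 (score 59.0) and chromosome 5 at 125519952 to 125521331 (score 58.0) had an e7.5 peak within 1.60 to 3.66 kb. The other 4 lay within 5 kb of an input peak. They included the highest score of all e9.5-only peaks, 199, at chromosome 8, 19984423 to 19985396, and a second peak of the same stretch at 19975495 to 19975699 (score 57.0), which lay 0.0780 and 0.0480 kb from input peaks. The remaining 2 were chromosome 6, 30122496 to 30125786 (score 66.0), and chromosome 7, 19297297 to 19298357 (score 60.0). Their nearest e7.5 peaks were 3.19 and 0.544 kb away, so allowing a gap of 1 kb would make the chromosome 7 peak shared.

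Most stage-only peaks lay more than 10 kb from any peak of the other stage. Of the e7.5-only peaks, 1684 of 2911 (57.8%) were more than 10 kb from any e9.5 peak and 523 (18.0%) more than 100 kb. Of the e9.5-only peaks, 2179 of 3300 (66.0%) were more than 10 kb from any e7.5 peak and 853 (25.8%) more than 100 kb. The median distance was 15.2 kb for e7.5-only and 28.4 kb for e9.5-only peaks. These distances were not compared with those of random positions, so they do not show that stage-only peaks stood apart from peaks of the other stage. Within 5 kb of an input peak of either stage lay 5.29% of e7.5-only and 5.52% of shared e7.5 peaks (two-sided Fisher's exact p = 0.711), and 6.18% of e9.5-only and 5.39% of shared e9.5 peaks (two-sided Fisher's exact p = 0.149).

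Peaks were also joined into longer regions, whose number and length were not compared with random placement. Joining peaks less than 12.5 kb apart gave 4751 regions at e7.5 and 5280 at e9.5. Regions of at least 5 peaks numbered 119 at e7.5 and 97 at e9.5. Of the e7.5 peaks inside them 462 of 734 (62.9%) were shared, against 59.3% of the e7.5 peaks elsewhere, and of the e9.5 peaks inside them 388 of 587 (66.1%), against 55.9% elsewhere; these differences were not tested. The longest at e7.5 spanned 87.3 kb of chromosome 15 (61884326 to 61971670) with 13 peaks, and the e9.5 list also had 13 peaks there. It was followed by 76.5 kb of chromosome 16 (95844485 to 95920996), with 13 peaks at either stage, and by 75.1 kb of chromosome 11 (117072007 to 117147094), with 15 peaks at e7.5 and 8 at e9.5. At e9.5 the longest spanned 71.6 kb of chromosome 9 (121210026 to 121281588), with 9 peaks at e9.5 and 6 at e7.5. Stretches of chromosomes 4 and 6 were among the 6 longest at both stages. That on chromosome 4 ran from 118754570 to 118815430 at e7.5 and from 118763380 to 118815494 at e9.5, with 12 peaks of the respective stage. That on chromosome 6 ran from 144969248 to 145027145 at e7.5, with 10 peaks, and from 144968776 to 145027070 at e9.5, with 6. These regions, and the clusters that follow, were chosen for length or peak number after the lists had been examined.

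Stage-only peaks gathered into clusters of their own. In each e9.5-only cluster of at least 5 peaks the highest score was below 35. In the e7.5-only clusters of that size the highest score ran from 28.0 to 60.0, with 47.0 in the largest. Peaks scoring below 35 were often called at 1 stage only, as the score bands above show, so many cluster members lay near the score minimum of 21. The largest e7.5-only cluster held 7 peaks over 35.4 kb of chromosome 7 (117774951 to 117810337), with no e9.5 peak inside it and an input peak between its members. A further 6 e7.5-only peaks lay on chromosome 11 between 117103331 and 117122350, inside the long region named above, without an e9.5 peak. The other 5 e7.5-only clusters of at least 5 peaks held 5 each. On chromosome 16 they lay at 92421385 to 92452576 and at 32706311 to 32724310, each with 1 e9.5 peak inside, and on chromosome 6 at 144999880 to 145025347, with 2 e9.5 peaks and an input peak inside. Those on chromosome 5 (101026627 to 101043842) and chromosome 14 (41714712 to 41730903) held no e9.5 peak, and an input peak lay within the latter. The largest e9.5-only cluster held 7 peaks over 29.5 kb of chromosome 15 (58806691 to 58836202), where the e7.5 list had 1 peak. It was followed by 6 e9.5-only peaks in 9.55 kb of chromosome 19 (4293530 to 4303078), without an e7.5 peak. The other 3 e9.5-only clusters of at least 5 peaks held 5 each, on chromosome 17 at 6953062 to 6978993 with 3 e7.5 peaks inside, on chromosome 17 at 29577518 to 29597043 with no e7.5 peak but an input peak inside, and on chromosome 15 at 96879599 to 96897609 with 2 e7.5 peaks inside. Of stage-only peaks with a stage-only neighbour at most 12.5 kb away, 883 of 1469 neighbouring pairs (60.1%) were of the same stage, against 50.3% on average and 56.3% at most when stage labels were permuted within chromosomes 100000 times (one-sided permutation p = 1e-05, the smallest these permutations can give). Clusters of at least 4 stage-only peaks numbered 22 at e7.5 and 15 at e9.5. Their total of 37 compared with 24.3 on average and 35 at most in 100 permutations.

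**Figure D2:**
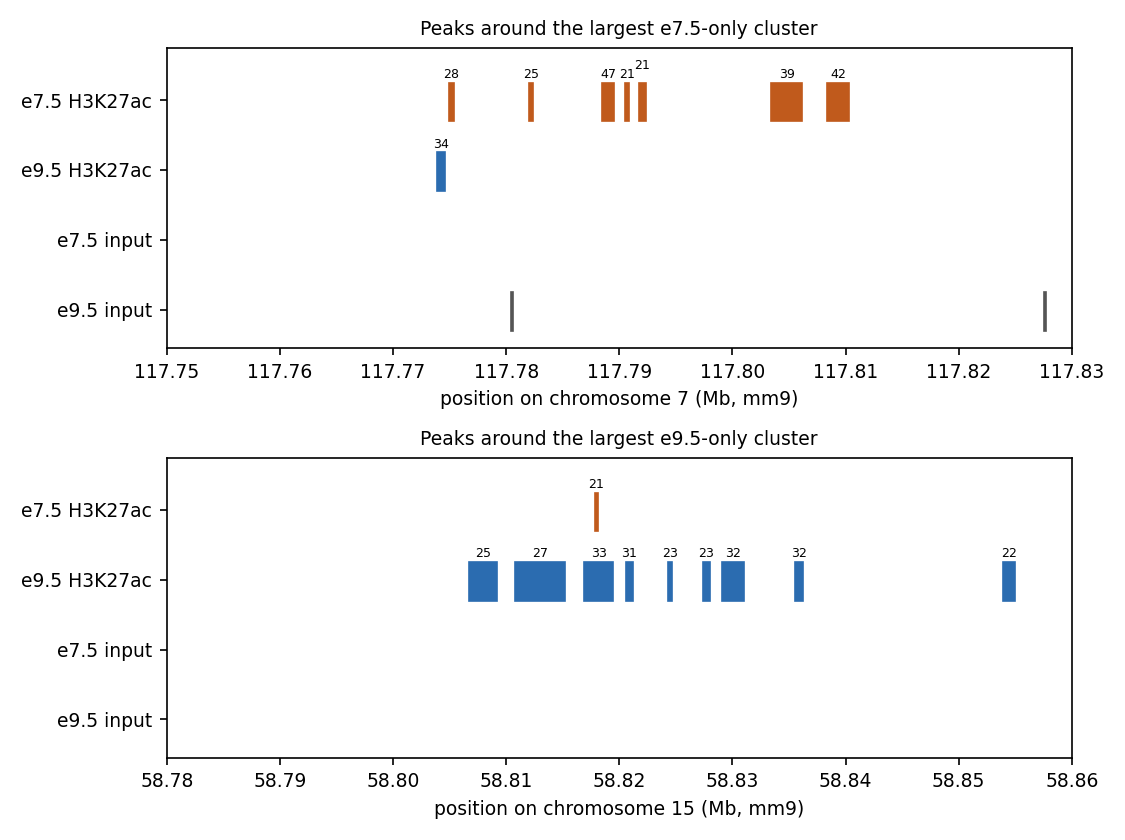
Peaks of the 4 lists (rows) in windows of 80 kb around the largest e7.5-only cluster on chromosome 7 (top) and the largest e9.5-only cluster on chromosome 15 (bottom); the horizontal axis is the mm9 position in Mb, boxes are peaks and each H3K27ac box carries the score the authors gave it. The top window holds 7 peaks at e7.5 and 1 at e9.5, the bottom window 1 at e7.5 and 9 at e9.5.

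Peak numbers of the stages also differed in single windows of 1 Mb. Chromosome 7 from 117 to 118 Mb held 17 e7.5 peaks and 8 e9.5 peaks, and chromosome 6 from 82 to 83 Mb held 10 and 2. In the other direction, chromosome 15 from 58 to 59 Mb held 3 e7.5 peaks and 15 e9.5 peaks, as did chromosome 5 from 144 to 145 Mb. Chromosome 4 from 134 to 135 Mb held 16 and 28, and chromosome 17 from 29 to 30 Mb held 12 and 24. These windows are the extremes of all 1 Mb windows and were not tested one by one.

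The last comparison set the H3K27ac lists against input DNA, the background of the same tissue. No H3K27ac peak overlapped an input peak in any of the 4 pairings of an H3K27ac list with an input list. Taking 3 counts as the limit that a count of 0 allows, the share was at most 0.0415% of 7224 e7.5 peaks and 0.0394% of 7620 e9.5 peaks. The exact binomial 95% intervals reached 0.0511 and 0.0484%. Such limits bound nothing if H3K27ac peaks on input were removed before deposit, which the labels do not record. Random placement of the e9.5 input peaks put them on 30.6 of the e9.5 H3K27ac peaks on average and on 16 at the least, so the planned one-sided test for an excess gave a permutation p of 1.00, while the lower tail, examined after the count was seen, gave a permutation p of 0.001. For the e7.5 pairing, random placement gave 1.81 overlaps on average, and 0 was within its range (lower-tail permutation p = 0.157). The input lists themselves agreed in part. Of the 466 e7.5 input peaks, 328 (70.4%) overlapped an e9.5 input peak, against 0.131% in random placements (one-sided permutation p = 0.001). Of the 7499 e9.5 input peaks, 261 (3.48%) overlapped an e7.5 input peak, against 0.00829% in random placements (p = 0.001 by the same permutation test). The small number of e7.5 input peaks limits that share.

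The 4 richest stretches of the e7.5 input list held 220 of its 466 peaks (47.2%), and the 4 richest of the e9.5 input list, in part other stretches, held 233 of its 7499 peaks (3.11%). On chromosome 2, 99 e7.5 input peaks lay within 155 kb (77707790 to 77862689) and 57 e9.5 input peaks within 174 kb (77687871 to 77862003), and neither H3K27ac list had a peak there. On chromosome 8, 71 e9.5 input peaks lay within 156 kb (19876931 to 20033097). Inside it, 31 e7.5 input peaks lay within 26.2 kb (19920455 to 19946607). The stretch of 156 kb held 3 e9.5 H3K27ac peaks, among them the e9.5-only peak with the score of 199, and 1 e7.5 H3K27ac peak.

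**Figure D3:**
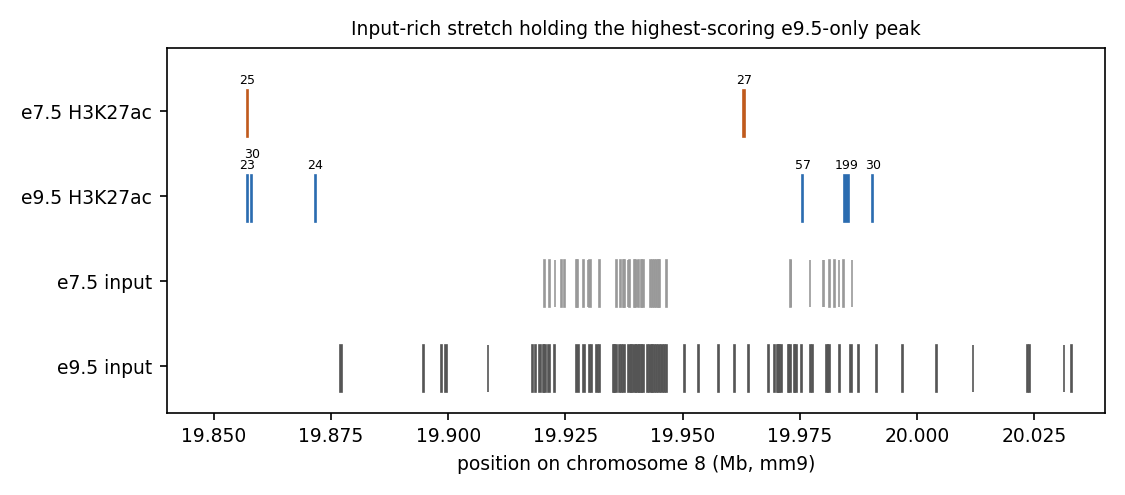
Peaks of the 4 lists (rows) over 200 kb of chromosome 8 (horizontal axis, mm9 position in Mb), drawn with a minimum line width so that narrow peaks can be seen, with the authors' scores above the H3K27ac peaks. The window holds 41 e7.5 and 71 e9.5 input peaks, and the e9.5 H3K27ac peak scoring 199 lies between input peaks.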

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

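All tests of this part were chosen after the results they measure, or the counts behind them, had been seen. The e9.5 input list held 192 peaks on the Y chromosome, where the e7.5 input list and both H3K27ac lists held none; the value stands out as a signal on a chromosome where no H3K27ac peak was listed. On chromosome 8, 71 e9.5 and 41 e7.5 input peaks lay in the 200 kb window around the highest-scoring e9.5-only H3K27ac peak. These numbers stand out as a signal in background DNA at either stage.

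No H3K27ac peak overlapped an input peak in any of the 4 pairings of lists. Random placement gave a mean of 30.3 overlaps for e9.5 H3K27ac with e9.5 input in the run over all pairings, and 29.6 for e7.5 H3K27ac with e9.5 input, so the absence there is not a matter of few peaks. Within 1 kb of an e9.5 input peak, without touching it, lay 100 e9.5 H3K27ac peaks, 2.18 times the random mean of 45.8 (one-sided permutation p = 0.001). For e7.5 H3K27ac peaks the number was 80 against 42.9. No avoidance of the surroundings of e9.5 input peaks showed in this comparison. Random placement spreads input peaks over whole chromosomes and no local shift of them was tried, so avoidance on a local scale is not decided. Around e7.5 input peaks the numbers decide nothing, with 4 e7.5 H3K27ac peaks (1.60 times the random mean, one-sided permutation p = 0.253) and 1 e9.5 H3K27ac peak (0.365 times, p = 0.930 by the same permutation test). A candidate explanation is that peaks lying on input of either stage were removed before deposit; the e7.5 H3K27ac list also lacks any overlap with the e9.5 input. No biological explanation was tested, and the removal itself is not recorded in the labels.

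Stage-only peaks had low scores: 68.1% of e7.5 peaks scoring 21 or 22 were stage-only, against 5.88% of those scoring 50 or more. Within 5 kb of an input peak lay 6.18% of e9.5-only and 5.29% of e7.5-only peaks, so most were not near a listed input peak. This does not decide on local input background as their source. Background too weak to be listed as an input peak was not measured, and H3K27ac peaks on input may have been removed before deposit. A first form of this test, the ratio of stage-only to shared peaks near input, gave 0.959 at e7.5 and 1.15 at e9.5 and was replaced after its values were seen. Chance crossing of the score minimum of 21 stays open and may account for many stage-only peaks. Of the e7.5 peaks scoring 50 or more, 30 had no e9.5 partner and 110 had one scoring 21 to 40; at e9.5 the numbers were 17 and 197, so peaks without a partner were fewer than partners in that range; the range is wide and the scores of the lists have no known common scale, so this count decides little. A change of acetylation between stages stays open as well, because there is no list per replicate to show how often a peak is missed by chance.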

How the results depend on the processing

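The sharing between stages stayed above random placement under all 10 alternatives tried for each stage, with shares from 39.7 to 64.9% of e7.5 peaks and from 37.7 to 61.0% of e9.5 peaks; the lowest came from asking that both peaks be covered by at least 50% and the highest from allowing a gap of 1 kb. Leaving out peaks on input removed none, so that setting tests nothing. Moving the other list by 20 to 200 kb, chosen after seeing the data, raised the random mean to 2.81% and 2.66%. Allowing a gap of 1 kb turned the e9.5 H3K27ac and input result from 0 to 1.31% of peaks, above the random mean of 0.998% (one-sided permutation p = 0.00400), because peaks next to input then count. The lower tail of the same comparison, chosen after seeing the data, passed the threshold at a share of 0 (permutation p = 0.001). The other settings of the input comparisons kept their side of the threshold. The same-stage share of neighbouring stage-only peaks ran from 58.7 to 76.4% over its 4 alternatives, all chosen after seeing the data. No paired analysis was possible because each group has 1 peak list and no value per replicate; leaving out each replicate was not run for the same reason. The promoter, gene and gene list results and their alternatives were not run without an mm9 annotation. Unknown depth and an unexplained score limit what a missing peak can show.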

Other observations

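Stage-only peaks leaned to e9.5 on chromosome 17, with 100 e7.5-only and 174 e9.5-only peaks (63.5% e9.5, against 53.1% over all chromosomes). Flipping whole 1 Mb blocks between stages, a test chosen after the counts were seen, gave a two-sided permutation p of 0.00161 and, adjusted by Benjamini-Hochberg over 20 chromosomes, 0.0322. With blocks of 2 Mb and 5 Mb, tried after that result, the adjusted permutation p was 0.110 and 0.0662, so chance over 20 chromosomes stays open. Leaving out the block from 29 to 30 Mb, picked for its excess of e9.5 peaks, could only weaken the result and gave 62.4% (adjusted permutation p = 0.0678). Chromosome 19 had 86 e7.5-only and 129 e9.5-only peaks (60.0%, adjusted permutation p = 0.665), and the X chromosome 59 and 49 (45.4%, adjusted permutation p = 0.665).

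Neighbouring stage-only peaks tended to belong to the same stage, a pattern looked for after clusters had been seen. The first 3 tests below were written down before the same-stage shares were known, and the test of pairs 1 to 2 Mb apart after those shares but before its own. Independent chance crossing of the score minimum is argued against as the whole source, since 60.1% of neighbours within 12.5 kb were of the same stage against at most 56.3% in permuted labels. Splitting of a region of up to 12.5 kb into several peaks is argued against as the whole source. Neighbours 12.5 to 50 kb apart gave 60.2% against at most 56.1% (one-sided permutation p = 1e-05, the smallest possible). Joined regions reached 87.3 kb, so such neighbours can lie in 1 region, and splitting of wider regions is not decided. Background at listed input peaks is argued against likewise, with 58.7% after leaving out peaks within 50 kb of one, against at most 57.8%. Background too weak to be listed was not measured, and the e7.5 input list held only 466 peaks, so other local background stays open. Pairs 1 to 2 Mb apart argue against a difference over 1 Mb or more, with 50.1% against a permuted mean of 50.3%. A change of acetylation that neighbouring regions share between e7.5 and e9.5 may account for the pattern and stays open as a hypothesis. Differences in GC content recovery or between library batches stay open as well, since the first was not tested and the second goes with stage.

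The same-stage share of all pairs of stage-only peaks fell with distance, from 59.5% of 4602 pairs up to 50 kb apart to 53.9% at 50 to 200 kb (one-sided permutation p = 0.001 for either), 50.9% at 200 to 500 kb (p = 0.114, permutation) and 49.3% at 500 to 1000 kb (p = 0.995, permutation). Among stage-only peaks in the higher-scoring part of their lists, 84 of 110 neighbouring pairs (76.4%) were of the same stage, against 50.1% on average and 70.0% at most in permuted labels.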
